A study of Mus musculus with 6 samples.

How the data were processed

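The data were 6 Affymetrix Mouse Genome 430 2.0 arrays of bone marrow macrophages from mice without TNF receptors 1 and 2, 3 with a mutant and 3 with a wild-type chimeric receptor. Per the labels' protocols, the cells were infected with retrovirus, selected with puromycin at 2 ug/ml for 3 days and treated for 24 hours, RNA of 6 dishes was pooled, and the preparation was made in 3 independent assays. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the assays used different mice. The sex-linked genes given in the results show another donor mix in assay 3 than in assays 1 and 2.

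The deposited values were intensities, 1 per probe set and array. The submitters' processing notes name GCOS and GCRMA without versions, and how they were combined is not given in the sources used here. The intensities lie on a linear scale and their 75th percentiles were 160 to 164 on the 6 arrays, so no further normalization was applied in the primary analysis. GCRMA estimates the background and normalizes between arrays, which makes arrays alike in distribution and compresses dim probe sets towards a floor. How far a shift of all genes was removed there cannot be told from the intensities.

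Of 45101 probe sets, 64 control probe sets were left out. The platform annotation gave 1 gene symbol for 34945 of the remaining 45037 probe sets, several for 932 and none for 9160. A probe set with several or none was tested and left unnamed. Through their gene identifiers 34741 were found in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. Positions of probe sets were not used here, and no coordinates are printed.

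Intensities were transformed to log2(value + 16), so fold changes are on that scale and understate the change of dim genes. A probe set was kept if it lay above the median (percentile 50) of its own array on at least 3 of the 6 arrays, which left 22497 probe sets, among them 10372 genes with 1 symbol. Differences were coded as mutant minus wild type and tested, two-sided, with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 without a block. Benjamini-Hochberg adjusted p-values under 0.05 counted as passing. Standard errors are limma's moderated ones from this fit without a block, so they also hold the differences between assays. A gene was represented by its kept probe set with the highest mean over all 6 arrays.

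Before the data were examined, 33 gene lists with 637 members were fixed, of which 52 members matched no symbol, together with the tests, the alternatives and the rule for named genes. The lists were tested with limma's camera, which compares a list with the other genes, with a preset correlation between genes of 0.01, for the 27 lists with at least 3 genes tested and not counting the sex-linked list, which only served to check the animals. Of these, 9 passed with the preset correlation and 0 with an estimated correlation, where the smallest adjusted p by camera was 0.261. The limma fry test, which asks whether the genes of a list move on balance in 1 direction, called 0 lists, with a smallest adjusted p of 0.440. Member counts were given both over all probe sets and adjusted over the list alone.

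The genes named were the highest and lowest passing genes without overlap between the groups. As none passed, they were filled to 5 in each direction by the smallest p among genes at least 1.5-fold apart without overlap. Up to 4 members of each list with the smallest p were named, together with Acp5, Ctsk, Mmp9, Calcr, Nfatc1, Dcstamp, Oscar, Itgb3, Atp6v0d2, Tnfrsf1a, Tnfrsf1b and Tnfrsf11a. Any other gene is said to be chosen after its values were seen.

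The groups share replicate numbers, and the labels describe 3 independent assays. The deviations from the group means of same-numbered arrays correlated across probe sets at 0.797, 0.671 and 0.845, and those of other mutant and wild-type arrays at -0.618 to -0.0138, so the numbers were taken to pair the arrays. Same-numbered arrays correlated at 0.982 to 0.991 over all kept probe sets and other arrays at 0.936 to 0.974.

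The limma steps were tested on simulated data made from the 22497 probe sets with the assay differences of these arrays. With 50 probe sets changed per fold size, the fit without a block recovered 7 at 2-fold, 29 at 4-fold, 46 at 16-fold and 49 at 32-fold, and the fit with the block 47, 48, 50 and 50. Of 22297 unchanged probe sets they called 0 and 7. The noise was drawn independently for each probe set and array. Its variances were limma's moderated ones from the fit with the block, which differ less between probe sets than unmoderated ones. The recovery may therefore be too high, and these rates need not hold for the real arrays. There Mmp9, 29.4-fold lower in the mutant, had an adjusted p of 0.182 by limma with the block. A fit that calls 0 probe sets thus does not show that none changed. In the camera simulation, 8 of 200 unshifted lists had a p under 0.05. These lists held randomly drawn genes with independent noise, while the estimated correlation ran from -0.137 to 0.990 in the real lists. The simulation therefore cannot show that camera with the preset correlation keeps its error rate for the real lists.

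Alternatives changed the filter, normalization, variance prior, array weights, block, choice of probe sets, fold threshold, adjusted p threshold, pseudocount and the arrays used. A floor on log2 values was planned only for a log2 scale and was not run, as the intensities are linear. Other splits of the 6 arrays were tested as well. Figures were drawn with matplotlib 3.10.9.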

Results

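Expression was measured with Affymetrix Mouse Genome 430 2.0 arrays in mouse bone marrow macrophages that carried a chimeric receptor. The cells came from mice lacking both TNF receptors. The receptor joined the outer part of TNF receptor 1 to the membrane and inner parts of RANK, the receptor through which RANK ligand drives macrophages to become bone-resorbing osteoclasts. In the wild-type group (n = 3 arrays) the inner part was intact, and in the mutant group (n = 3 arrays) its IVVY motif carried inactivating mutations. Both groups received M-CSF at 44 ng/ml and TNF at 10 ng/ml for 24 hours, TNF being the ligand of the receptor's outer part. Each array held RNA pooled from 6 dishes, and the arrays came from 3 independent assays with 1 mutant and 1 wild-type array of each number. The study asked which genes the IVVY motif regulates in macrophages. The median intensity was between 8.86 and 9.38 on each array, and 42.8% to 44.1% of probe sets lay above an intensity of 16. The number of arrays limits the precision of all values below. The standard errors (SE) come from a fit that leaves out the assay, so they also hold the differences between assays.

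Several genes of the osteoclast programme had lower intensities in the mutant cultures. Mmp9, a matrix-degrading protease of osteoclasts, had an intensity of 167 ± 178 (SD, n = 3) in the mutant and 4513 ± 3139 (SD, n = 3) in the wild type, a 29.4-fold lower level on the log2(value + 16) scale. Ctsk, the collagen-degrading cathepsin K, had 350 ± 351 against 4281 ± 2707 (SD, n = 3 each), a 14.1-fold difference. Acp5, the tartrate-resistant acid phosphatase used to stain osteoclasts, had 514 ± 299 against 5901 ± 3135 (SD, n = 3 each), an 11.6-fold difference. Dcstamp, needed for the fusion of osteoclast precursors, was at 13.8 ± 1.48 against 113 ± 75.6 (SD, n = 3 each).

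Of the 23 osteoclast genes tested, 18 had a lower and 5 a higher mean in the mutant, with a median log2 difference of -0.97, and 16 were lower in every pair of same-numbered arrays. No osteoclast gene passed the limma test over all 22497 probe sets, while 9 passed, all lower, adjusted over the list alone. These 9 were Acp5 (log2 difference -3.54 ± 0.59 SE), Jdp2 (-2.08 ± 0.37), Mmp9 (-4.88 ± 0.89), Dcstamp (-1.97 ± 0.40), Ctsk (-3.82 ± 0.81), Slc9b2 (-1.77 ± 0.39), Myo1d (-1.46 ± 0.38), Rab38 (-1.38 ± 0.36) and Src (-1.16 ± 0.33). Jdp2 is a transcription factor of the AP-1 family and Src a kinase needed for bone resorption. Most mutant values of Dcstamp, Myo1d, Rab38 and Src lay near the floor, and the size of their differences depends on the pseudocount. With the replicate number as a block 10 passed over the list, as Car2 and Ppargc1b were gained (limma, adjusted p = 0.0453 each) and Myo1d was lost (adjusted p = 0.0525). The values of 12 of the 23 osteoclast genes did not overlap between the groups, all lower, where chance gives 10% for arrays without shared assays. Against the other genes the list was lower by camera (adjusted p = 4.87e-23 with the preset correlation), but its adjusted p = 0.261 with an estimated correlation. The count of 9 was 1 without mutant array 1, 3 without mutant array 2, and 5 with a pseudocount of 64 or the filter at the 70th percentile.

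**Figure D1:**
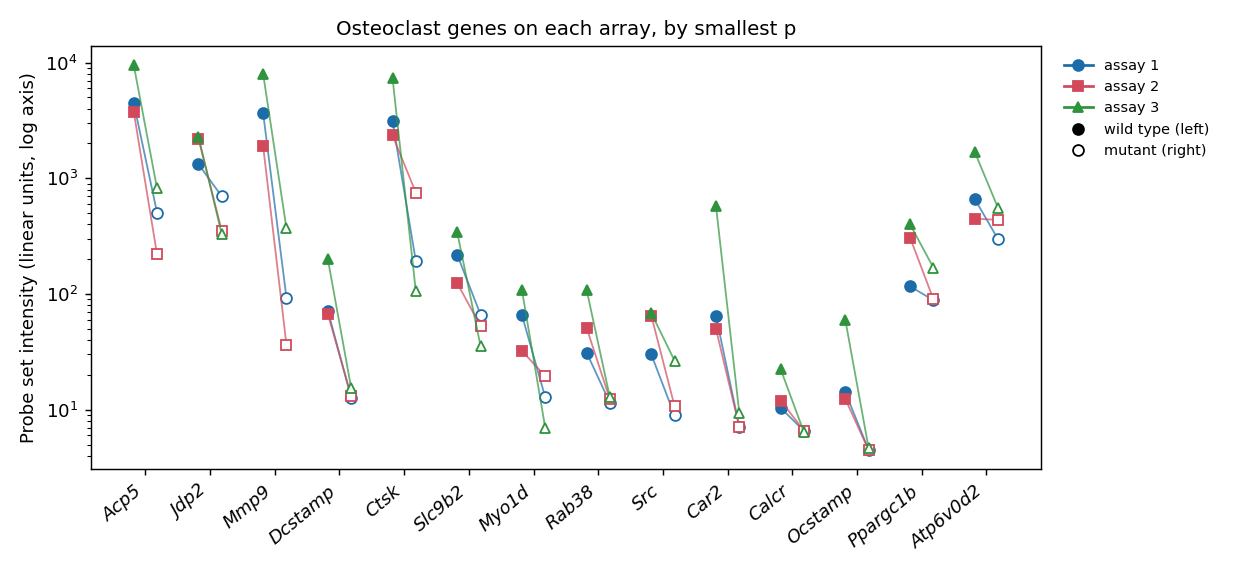
Intensity of the 14 osteoclast genes with the smallest limma p on each array (vertical log axis, linear intensity units), with filled symbols for wild type, open symbols for mutant, and lines joining the 2 arrays of an assay. For Acp5 the 3 wild-type arrays lay at 3745 to 9497 and the 3 mutant arrays at 220 to 818.

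Other osteoclast genes did not pass over the list without the block. Car2, the carbonic anhydrase that supplies protons for resorption, and Ppargc1b, a coactivator of mitochondrial genes, were named after their values were seen. Car2 was at 7.91 ± 1.33 in the mutant and 230.1 ± 299.6 in the wild type (SD, n = 3 each; limma, adjusted p = 0.0645 over the list). Its mutant values lay near the array medians, so the size of the difference is not given. Ppargc1b differed by -1.04 ± 0.50 SE on the log2 scale (limma, adjusted p = 0.154 over the list). Calcr, the calcitonin receptor, was near background in both groups, at 6.51 ± 0.113 against 14.9 ± 6.52 (SD, n = 3 each). Atp6v0d2, a proton pump subunit of osteoclasts, had a log2 difference of -0.91 ± 0.53 SE. The probe sets of Nfatc1, the transcription factor that leads osteoclast formation, disagreed. The brightest differed by 0.02 ± 0.10 SE, while 2 others differed by -1.03 ± 0.23 and -0.91 ± 0.23. The last of these read 8.71 to 16.3 on the mutant arrays, near the floor. Another, near the floor in both groups, differed by -0.15 ± 0.09, and 1 below the filter by -0.71. Except for the brightest, each was lower on all mutant arrays than on any wild-type array. Oscar and Itgb3 fell below the filter on dim probe sets, and the Oscar probe sets read 29.5 and 23.1 on wild-type array 3 and at most 6.49 on the other arrays.

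The receptor genes of the design showed no difference that passed. Tnfrsf1a, which encodes TNF receptor 1, read 691 to 1069 on the mutant arrays and 678 to 1045 on the wild-type arrays, with a log2 difference of 0.00 ± 0.25 SE. Tnfrsf11a, which encodes RANK, differed by -0.23 ± 0.33 and -0.08 ± 0.28 on 2 probe sets, and Tnfrsf1b, which encodes TNF receptor 2, by -0.28 ± 0.34 and -0.10 ± 0.17. Where these probe sets lie relative to the deleted parts of the receptor genes and to the chimeric receptor is not given in the sources used here, so their values check neither the knockouts nor the amount of the chimeric receptor. Of the 21 receptor and pathway genes tested, 0 passed adjusted over the list alone or over all probe sets, and the list did not pass camera (adjusted p = 0.120, but 0.0193 with each gene taken as the mean of its probe sets).

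Over all 22497 probe sets, the strongest differences were towards lower levels in the mutant. On the mean, 14 probe sets were at least 4-fold lower and 0 at least 4-fold higher, and 25 probe sets were at least 2-fold lower in every pair against 0 at least 2-fold higher. The 25 were 48 without the filter on dim probe sets or without a pseudocount, 46 with a pseudocount of 1, 10 with the filter at the 70th percentile and 11 with a pseudocount of 64, each against 0 higher. Without both arrays of assay 1, 2 or 3 there were 60, 40 and 38 lower against 1, 5 and 21 higher. These fold counts were chosen after the values were seen. Gpc1, a cell surface proteoglycan, had the smallest p, at 20.7 ± 2.59 in the mutant against 113 ± 22.8 in the wild type (SD, n = 3 each), a log2 difference of -1.80 ± 0.16 SE. Grk3, a receptor kinase, differed by -1.99 ± 0.29, and the acid phosphatase gene Acpp by -1.39 ± 0.21. The metallothionein genes Mt2 and Mt3 differed by -1.33 ± 0.21 and -0.84 ± 0.14.

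Higher in all 3 mutant arrays were Lpl, the lipoprotein lipase (11260.0 ± 1821 against 7368 ± 678, SD, n = 3 each), Marcksl1 (log2 difference 0.63 ± 0.22 SE), Hmga2 (0.85 ± 0.30), Lin9 (0.59 ± 0.23) and Cmbl (0.96 ± 0.51). None of these 10 genes passed. By limma 0 probe sets passed after adjustment, the smallest adjusted p was 0.99998, and 146 lower and 52 higher probe sets had an unadjusted p under 0.05, 198 in all. Chance gives 1125 for arrays without shared assays, but in simulated data with assay differences the same limma fit gave 45 of 22297 unchanged probe sets at such a p. Without mutant array 3 limma gave 267 lower and 491 higher such probe sets. With the replicate number as a random block limma called 1, Gpc1 (adjusted p = 0.0499). The limma fit with the replicate number as a fixed block called 0, with 626 lower and 563 higher at an unadjusted p under 0.05 and a smallest adjusted p of 0.0792. Of all probe sets, 3.06% had no overlap between the groups, where chance gives 10% for arrays without shared assays.

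The assays differed more than the groups. Replicate number accounted for 81.9% of the total sum of squares and group for 7.69%. Genes of stromal cells separated assay 3 from the others in both groups. Sparc, a matrix protein of connective tissue, read 1325 and 1061 on mutant and wild-type array 3 and at most 57.4 on the other 4 arrays. Col3a1, a fibrillar collagen, read 524 and 380 there and at most 31.9 elsewhere. Xist, the transcript of the inactive X chromosome in female cells, read 10.5 and 8.82 on the arrays of assay 3 and at least 3308 elsewhere on its brightest probe set. The Xist probe sets disagreed in assay 2, where the brightest read 3962 in the mutant and 3308 in the wild type and another 1322 and 2827, while in assay 1 they read 5524 and 9152, and 1827 and 3426. The Y-linked Eif2s3y read 12.9 on wild-type array 1 but 308 on mutant array 1, while it was closer within the pairs of assay 2 (349 and 227) and assay 3 (1368 and 1436). With Xist near background and Eif2s3y brightest on both its arrays, assay 3 had another mix of donors than assays 1 and 2.

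**Figure D2:**
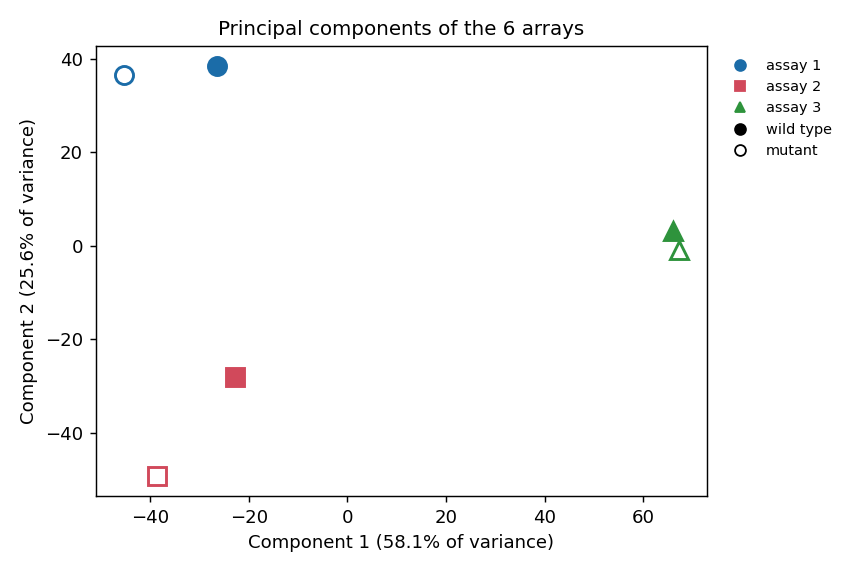
First and second principal components of the 6 arrays over the 22497 probe sets tested (58.1% and 25.6% of the variance), with open symbols for mutant and filled symbols for wild type. The 2 arrays of each assay lie near each other, and assay 3 stands apart on the first component.

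Of 24 target genes of NF-kB, the transcription factor activated by RANK and TNF receptors, 19 had a lower and 5 a higher mean in the mutant, the median log2 difference was -0.43, and 17 were lower in every pair. Traf1, an adaptor of TNF receptor signalling, was at 44.1 ± 18.9 against 419 ± 343 (SD, n = 3 each), a 6.22-fold lower level. Traf2 differed by -0.47 ± 0.10 SE, Bcl3 by -0.70 ± 0.28 and Birc2, named after its values were seen, by -0.78 ± 0.40. The list passed camera with the preset correlation (adjusted p = 2.10e-09), but not with an estimated correlation (camera, adjusted p = 0.397) or by fry (adjusted p = 0.870). By limma 0 members passed over all probe sets and 0 adjusted over the list alone, while 4 passed over the list, all lower, with the replicate number as a block (Traf1, Traf2, Bcl3 and Birc2).

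Inflammatory cytokines and chemokines went both ways. Cxcl3, a chemokine that attracts neutrophils, was at 287 ± 178 in the mutant against 4587 ± 3536 in the wild type (SD, n = 3 each), a 12.9-fold lower level, while Ccl2, which attracts monocytes, differed by 0.56 ± 0.45 SE on the log2 scale. Of 16 tested, 9 were lower and 7 higher, and the list did not pass camera (adjusted p = 0.120, but 0.00272 without wild-type array 2). By limma 0 passed over all probe sets and 0 adjusted over the list alone. With the replicate number as a block, 3 lower members (Cxcl3, Ccl9 and Il1rn) and 1 higher member (Ccl2) passed over the list.

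Interferon-stimulated genes had a lower mean in the mutant for all 35 tested, with a median log2 difference of -0.48. The pair medians were -1.13 in assay 1, -0.02 in assay 2 and -0.49 in assay 3, and 17 genes were lower and 0 higher in every pair. Tap1, a peptide transporter of antigen presentation, differed by -0.54 ± 0.29 SE and Stat2, a factor of interferon signalling, by -0.86 ± 0.97. In assays 1, 2 and 3 Tap1 differed by -0.75, 0.19 and -1.05, and Stat2 by -0.92, -1.07 and -0.58. The list passed camera (adjusted p = 9.58e-06), with adjusted p = 0.726 with an estimated correlation. In camera it no longer passed without mutant array 1 (adjusted p = 0.396) or mutant array 2 (adjusted p = 0.193), nor without wild-type array 3, where its direction turned (adjusted p = 0.314). By limma 0 members passed over all probe sets or adjusted over the list alone.

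Of 30 genes of oxidative phosphorylation, which encode the respiratory chain and ATP synthase, 29 had a lower mean in the mutant, with a median log2 difference of -0.18. The pair medians of this list were -0.015, -0.257 and -0.279 in assays 1, 2 and 3, and 16 genes were lower in every pair. Atp5b, a catalytic subunit of ATP synthase, differed by -0.38 ± 0.13 SE. Of the 16 vacuolar ATPase subunits, which acidify lysosomes and the resorption space, 13 were lower, with a median of -0.13, and Atp6v1b2 differed by -0.29 ± 0.17. Both lists passed camera (adjusted p = 7.31e-12 and 3.53e-04), each with adjusted p = 0.397 with an estimated correlation. The vacuolar ATPase list did not pass camera without wild-type array 3 (adjusted p = 0.103). By limma 0 members of either list passed over all probe sets or adjusted over the list alone.

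Of 14 genes of the NRF2 response to oxidative stress, 11 were lower, with a median log2 difference of -0.27. The pair medians were -0.019, -0.527 and -0.107 in assays 1, 2 and 3. Slc7a11, the cystine transporter, differed by -1.59 ± 0.61 SE, the quinone reductase gene Nqo1 by -1.18 ± 0.58, and Srxn1 by -0.60 ± 0.16. Slc7a11 was dim, at 33.7, 7.88 and 23.5 on mutant arrays 1, 2 and 3, so the size of its difference depends on the pseudocount. Of 13 p53 target genes, 12 were lower, with a median of -0.29, and the death receptor gene Fas differed by -0.66 ± 0.25 SE. The p53 pair medians were -0.207, -0.647 and -0.032 in assays 1, 2 and 3. The lists passed camera (adjusted p = 9.53e-05 for NRF2 and 3.21e-04 for p53), with adjusted p = 0.494 and 0.463 with an estimated correlation. The NRF2 list did not pass camera without mutant array 2 (adjusted p = 0.101). The p53 list did not pass camera without mutant array 1, mutant array 2 or wild-type array 3 (adjusted p = 0.179, 0.165 and 0.150). By limma 0 members of these lists passed over all probe sets or adjusted over the list alone, and with the replicate number as a block 2 NRF2 genes, Slc7a11 and Nqo1, passed over the list.

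The camera test placed 2 lists higher in the mutant. Of 20 cholesterol synthesis genes 19 had a higher mean, with a median log2 difference of 0.19 and pair medians of 0.086, 0.420 and 0.074 in assays 1, 2 and 3. Hmgcs1, an early enzyme of the pathway, differed by 0.32 ± 0.30 SE and Sc5d, a late one, by 0.24 ± 0.12. All 3 adipocyte markers tested were higher, Lpl by 0.60 ± 0.16 SE, Pparg by 0.50 ± 0.36 and Fabp4 by 0.26 ± 0.35. Macrophages also express these 3 genes. Both lists passed camera (adjusted p = 0.01004 for cholesterol synthesis and 8.31e-04 for adipocyte markers), with adjusted p = 0.763 and 0.280 with an estimated correlation. Without the filter on dim probe sets the adipocyte list did not pass camera (adjusted p = 0.0764). The cholesterol synthesis list did not pass camera without mutant array 1, mutant array 2 or wild-type array 3 (adjusted p = 0.217, 0.853 and 0.930). By limma 0 members of these lists passed over all probe sets, and Lpl was the 1 member that passed adjusted over the list alone, where it had adjusted p = 0.0345, or 0.0602 with the replicate number as a block.

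**Figure D3:**
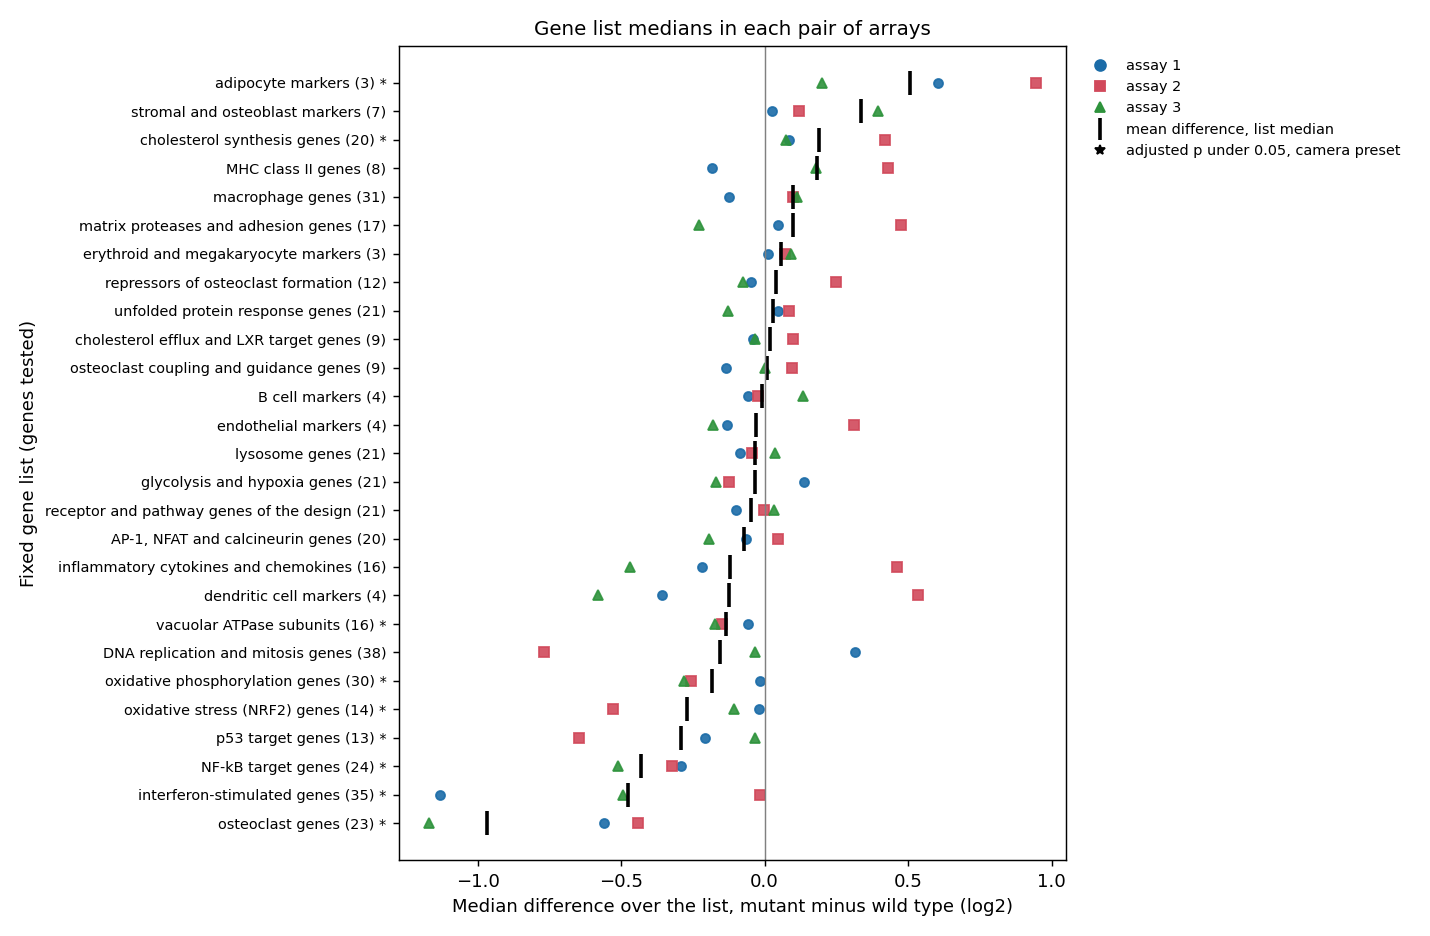
Median log2 difference, mutant minus wild type, of each gene list in each assay (coloured symbols) and of the mean over the assays (black bars), with the number of genes tested in parentheses and a star for lists that passed camera with the preset correlation. The osteoclast list has medians of -0.56, -0.44 and -1.17 in assays 1, 2 and 3.

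C1qb, a complement component made by macrophages, read 36909 ± 2299.7 (SD, n = 3) in the mutant and 33362 ± 4654 (SD, n = 3) in the wild type, and the membrane protein gene Gpnmb 22521 ± 819 and 24731 ± 1827. Marco, a scavenger receptor, had a log2 difference of 1.62 ± 1.17 SE that did not pass, with pair differences of 2.60, -1.42 and 3.70 in assays 1, 2 and 3. It read 205, 183 and 451 on mutant arrays 1, 2 and 3, and 517 on wild-type array 2 against at most 20.5 on the other wild-type arrays. Of 31 macrophage genes 20 had a higher and 11 a lower mean, with a median log2 difference of 0.10, and the list did not pass camera (adjusted p = 0.196, but 0.0312 without mutant array 2 and 0.0389 without wild-type array 1, with a higher direction in both).

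**Figure D4:**
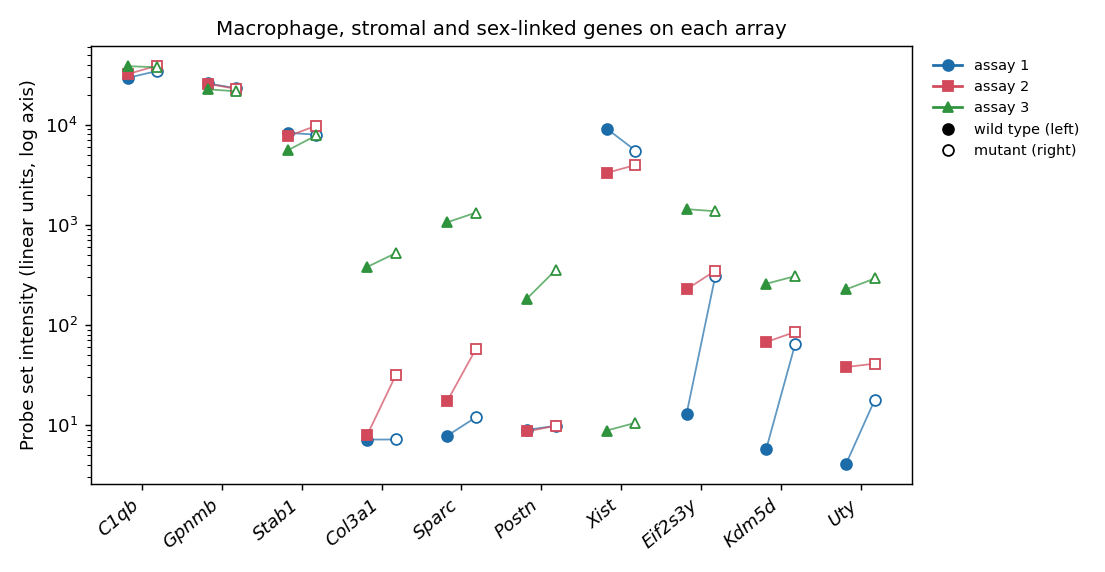
Intensity of macrophage, stromal and sex-linked genes on each array (vertical log axis, linear intensity units), with filled symbols for wild type, open symbols for mutant, and lines joining the 2 arrays of an assay. Sparc and Col3a1 stand above the other assays on both arrays of assay 3, and Xist lies below them.

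Matrix proteases and adhesion genes went both ways, 8 lower and 9 higher of 17, with a median log2 difference of 0.10 and a mean of -0.25. Mmp14, a membrane-bound protease, differed by -1.59 ± 0.61 SE and Fn1, which encodes fibronectin, by 0.98 ± 0.68. In limma Mmp9 was the 1 member that passed adjusted over the list alone, and with the replicate number as a block Fn1 passed too, as a higher gene. Of 20 AP-1, NFAT and calcineurin genes 14 were lower, Fosl2 by -0.60 ± 0.21 SE, and Jdp2 was the 1 member that passed limma adjusted over the list alone, where the fit with the block called 0. By camera neither list passed (adjusted p = 0.678 and 0.0912), although the second had adjusted p = 0.0448 without wild-type array 1 and 0.00554 with each gene taken as the mean of its probe sets.

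The other lists tested did not pass camera and had 0 members that passed limma over all probe sets or adjusted over the list alone. Their adjusted p by camera was 0.160 for 21 lysosome genes, 0.832 for 12 repressors of osteoclast formation, 0.120 for 8 MHC class II genes and 0.696 for 38 DNA replication and mitosis genes. It was 0.832 for 9 cholesterol efflux and LXR target genes, 0.539 for 21 glycolysis and hypoxia genes, 0.832 for 21 unfolded protein response genes and 0.832 for 9 osteoclast coupling and guidance genes. Among markers of other cells it was 0.832 for 4 B cell, 0.770 for 4 dendritic cell, 0.832 for 7 stromal and osteoblast, 0.832 for 4 endothelial and 0.696 for 3 erythroid and megakaryocyte genes. Other settings changed camera calls of these lists. Lysosome genes passed as lower with array weights on all arrays (adjusted p = 0.0266 by camera), without mutant array 3 (0.00582) and without both arrays of assay 3 (0.0110), and glycolysis genes without mutant array 1 (0.0497). MHC class II genes passed camera as higher without mutant array 2 (adjusted p = 0.0404) or wild-type array 1 (3.45e-05), and stromal markers without wild-type array 3 (0.0246). The DNA replication list passed camera as lower without mutant array 1 (adjusted p = 3.05e-06) or wild-type array 3 (0.0198), but as higher without mutant array 3 (5.32e-04) or wild-type array 1 (8.96e-04). Only 2 T cell, 2 neutrophil and 2 haematopoietic progenitor markers and 0 NK cell or mast cell and basophil markers were bright enough to test, so these lists had no set test. The DNA replication list had a median of -0.15, a mean of -0.03 and a test direction towards higher. The medians, means and test directions also differed in sign for the cholesterol efflux, unfolded protein response, coupling and guidance, and B cell lists.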

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

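The alternatives without a pseudocount, with a random block, with the block and an estimated correlation together, and without both arrays of an assay, and all tests of the count in every pair, were chosen after seeing the data. By limma, 0 probe sets passed in the primary analysis and in every alternative except the random replicate block (duplicateCorrelation), which called 1, Gpc1 (adjusted p = 0.0499, where the smallest adjusted p in any other limma fit was 0.0792). The fixed replicate block also called 0 probe sets, left 9 lists passing camera and gave 10 osteoclast genes adjusted over the list alone (Car2 and Ppargc1b gained, Myo1d lost). Apart from these and the members of other lists given with the block in the results, it changed no other call. The 25 probe sets at least 2-fold lower in every pair became 48 without the filter, 10 with the filter at the 70th percentile, 46 with a pseudocount of 1, 11 with a pseudocount of 64 and 48 with none. Without both arrays of assay 1, 2 or 3 they were 60, 40 and 38, as 1 pair fewer is required, with 1, 5 and 21 at least 2-fold higher.

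The 9 lists that passed camera became 0 with an estimated correlation and 0 with it and the replicate block. The adipocyte list failed (camera, adjusted p = 0.280) although its estimated correlation of -0.042 lay below the preset 0.01. With the block, the NF-kB and vacuolar ATPase lists failed at -0.018 and -0.0048 (camera, adjusted p = 0.475 each). A failure with an estimated correlation thus does not by itself show that correlated genes made the preset calls. The osteoclast list kept its lower direction in all 25 alternatives (adjusted p by camera 1.71e-27 to 0.475) and failed only with an estimated correlation (0.261, and 0.475 with the replicate block). Its 9 members passing over the list alone by limma became 5 at the 70th percentile, 5 with a pseudocount of 64, 1, 5 and 3 without both arrays of assay 1, 2 and 3, and 1 (without mutant array 1) to 9 with single arrays left out, where fewer arrays were tested. The osteoclast, NF-kB, oxidative phosphorylation and adipocyte lists, 4 of the 9, passed camera without any single array. Without both arrays of assay 1, interferon genes no longer passed camera (adjusted p = 0.0999), and without those of assay 2 neither did cholesterol synthesis (0.438), NRF2 (0.0532) or p53 genes (0.105). Of the 18 lists that did not pass, 10 passed in at least 1 alternative, 8 of them without a single array. The other 2 were dendritic cell markers (0.00181 by camera without both arrays of assay 2) and the receptor list (0.0193 as the mean of probe sets). Of the 8, some passed camera in other alternatives too. Without both arrays of assay 1 these were MHC class II (adjusted p = 2.78e-05), macrophage (0.00613) and glycolysis genes (0.0335). Without assay 2 they were cytokines (5.08e-05) and AP-1 genes (0.0277, and 0.00554 as the mean of probe sets). Without assay 3 they were lysosome (0.0110, and 0.0266 with array weights) and DNA replication genes (0.0142).

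The camera direction turned in 60 of 646 list alternatives, all but 3 of them between values that did not pass. With the replicate block it turned for cholesterol efflux, unfolded protein response and B cell lists (adjusted p = 0.890 each by camera) and matrix genes (0.914). With quantile normalization as well these were 0.879 for the first 3 lists and 0.937 for matrix genes, and with an estimated correlation 0.921 for all 4. Without assay 1 it turned for DNA replication (0.0719), unfolded protein response (0.786), coupling (0.471), B cell (0.962) and dendritic cell lists (0.786). Without assay 2 it turned for repressors of osteoclast formation (0.212), cholesterol efflux (0.786) and unfolded protein response (0.653), and without assay 3 for cytokines (0.811), macrophage (0.777), glycolysis (0.583), matrix (0.330) and endothelial lists (0.622). It also turned for cholesterol efflux at the 70th percentile (0.985), for stromal markers without the filter (0.823) and with array weights (0.880), for glycolysis and endothelial lists with array weights (0.954 each) and for endothelial markers as the mean of probe sets (0.913).

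With single arrays left out, lists whose direction turned had adjusted p by camera of 1.42e-16 to 0.396 for interferon genes (turned without wild-type array 3, 0.314) and 3.05e-06 (mutant array 1, turned) to 0.761 for DNA replication, which also turned without wild-type array 3 (0.0198). They were 0.335 to 0.866 for repressors of osteoclast formation, 0.00272 (wild-type array 2) to 0.606 for cytokines, 3.45e-05 (wild-type array 1) to 0.944 for MHC class II, 0.0312 (mutant array 2) to 0.944 for macrophage genes, 0.103 to 0.825 for cholesterol efflux and 0.0497 (mutant array 1) to 0.900 for glycolysis. For unfolded protein response they were 0.435 to 0.920, for matrix genes 0.161 to 0.963, for coupling 0.285 to 0.963, for B cell 0.320 to 0.853, for dendritic cell 0.110 to 0.700, for stromal 0.0246 (wild-type array 3) to 0.586 and for endothelial markers 0.188 to 0.902.

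Named genes changed sign in 15 of 1436 cases. Nfatc1 was -0.0074 with array weights, -0.52 as the mean of its probe sets, -0.0017 and -0.0076 without assays 2 and 3, and -0.018 to 0.093 with single arrays left out. Tnfrsf1a was -0.030 and -0.0087 without assays 1 and 3 and -0.19 to 0.19 with single arrays left out, Tnfrsf1b -0.51 to 0.0084, and Tnfrsf11a 0.25 without assay 3 and -0.49 to 0.088. Apart from the smaller numbers of arrays and pairs, the cause was not tested. The floor on log2 values was not run, and camera takes no random block. Signal near background limits Calcr, Oscar, Itgb3, Dcstamp, Car2, Myo1d, Rab38, Src, Cd200, Serinc2 and Htra1, as most of their mutant values lie near the floor, and the size of their differences depends on the pseudocount.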

Other observations

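The genes of this paragraph were chosen after their values were seen. The 25 probe sets at least 2-fold lower in every pair held 21 named genes, of which 6 were on the osteoclast list and 12 on no list. Cd200, a membrane glycoprotein of the immunoglobulin family, read 6.01 to 12.1 on the mutant arrays and 42.5 to 151 on the wild-type arrays. Cdkn2b, a cell cycle inhibitor, had a log2 difference of -1.85 ± 0.48 SE and read 31.7 to 79.5 against 120.3 to 386. A dimmer probe set of Malt1, a protease and scaffold of NF-kB signalling, differed by -1.53 ± 0.72, and its brightest by -1.16 ± 0.41. Cttn, which encodes the actin-binding cortactin, differed by -1.13 ± 0.55, with pair differences of -1.13, -1.08 and -1.17 in assays 1, 2 and 3. The processing enzyme gene Cpe differed by -2.35 ± 1.14, with pair differences of -2.18, -2.21 and -2.66. Within each group Cpe and the secreted protease gene Htra1 were brightest on array 3 (Cpe at 182 and 1234, Htra1 at 56.7 and 818 in mutant and wild type). Serinc2, a membrane protein gene, read 6.95 to 9.38 on the mutant arrays. The mutant values of Cd200 and Serinc2, and those of Htra1 on arrays 1 and 2, lie near the array medians of 8.86 to 9.38, so the size of their differences is not given. None passed limma over all probe sets. The smallest adjusted p with the replicate block (limma, 0.0792) belonged to a probe set annotated with 2 gene symbols and therefore unnamed, with a log2 difference of -3.26.

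The tests of the osteoclast, interferon and stromal patterns below, and the count of probe sets 2-fold apart in every pair, were chosen after the values were seen, while the other counts over splits of the arrays were planned before. For the lower osteoclast genes, stromal cells in assay 3 would leave the difference to that assay, but 17 of the 23 tested genes were lower in both assay 1 and assay 2. An unequal mix of male and female donor cells in pair 1 alone is argued against by the 16 of 23 genes lower in both assay 2 and assay 3. A mix in pairs 1 and 2 as the whole cause is argued against by pair 3, where the osteoclast median was -1.17 while Eif2s3y differed by -0.07 and the 2 brighter Xist probe sets, near background there, by -0.03 and 0.10. The probe sets of the Y-linked Uty differed there by -0.02 to 0.47 and those of Kdm5d by 0.0006 to 0.24. A lower share of macrophage lineage cells large enough for the osteoclast median of -0.97 would lower macrophage genes by about as much, but the median of the 31 tested was 0.10. An effect of the IVVY mutation on osteoclast genes is a hypothesis that remains, and a lower amount of the mutant receptor stays open beside it, as the arrays gave no measure of the construct.

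The lower interferon-stimulated genes may reflect differences between single cultures that do not follow the mutation. The pair median nearest to 0 was -0.017, in assay 2, where an equal effect of the mutation on all cultures would be seen as well. That median does not speak for each gene, as 17 of the 35 tested were lower and 0 higher in every pair. The estimated correlation of this list was 0.902, or 0.664 with the replicate block, so its genes do not count as independent of each other. With 3 pairs that differ this much, an effect of the mutation that varies between assays stays open. Other passing lists also had a pair median near 0. In assay 1 it was -0.015 for oxidative phosphorylation, -0.019 for NRF2 and -0.058 for vacuolar ATPase genes, and in assay 3 -0.032 for p53 genes. Differences between single cultures were not tested for these lists and stay open there as well.

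For the stromal genes on both arrays of assay 3, stromal cells carried into assay 3 from the marrow are a candidate source. Of the 18 markers measured, 7 were at least 4-fold higher on both arrays of assay 3 than on every other array, on the log2(value + 16) scale. Of all genes 50 of 18193 (0.275%) were. Genes of this paragraph were named after their values were seen. The brightest were Acta2 at 2928 and 2273 and Col1a2 at 1719 and 1109 on mutant and wild-type array 3. On that scale the dimmer Pdgfrb and Loxl1 did not count. Pdgfrb read 52.2 and 40.6 there against at most 8.32 elsewhere, and Loxl1 66.7 and 41.7 against at most 4.35. The osteoblast markers Sp7, Ibsp and Alpl were at background (at most 7.85) on every array, which does not tell whether other stromal cells were present. As the count depends on the scale, it does not settle the source. Puromycin selected infected cells and would remove uninfected ones, but which cell types were infected was not measured. No biological explanation of the stromal genes was tested.

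The 6 arrays make 10 splits into groups of 3, too few for a share under 0.05. Over these, 10 splits called as many probe sets as the real one by limma, as each called 0 (highest other 0), with 67 to 3796 at an unadjusted p under 0.05. The 9 osteoclast genes adjusted over the list alone came from 1 split, the real one (highest other 0). Camera with the preset correlation did not single out the real split, as the osteoclast list also passed in others. In the others that part all 3 pairs its adjusted p by camera was 5.75e-08, 0.00550 and 0.838, against 4.87e-23 in the real one. In splits that put both arrays of an assay together it was 0.00105 to 0.477. In 4 of the splits at least 9 lists passed camera. The highest other number was 10, in 2 splits that follow the assays, and another split that parts all 3 pairs also gave 9, while the real split gave 9 with the replicate block too. Compared with the 4 splits that part all 3 pairs, the real one alone (1 of 4) had 25 probe sets at least 2-fold apart in 1 direction in every pair, and the highest of the others had 3. Without a block the others that part the pairs gave 67, 100 and 160 probe sets at an unadjusted p under 0.05 by limma, against 198 in the real split. With the replicate block, limma gave 1189 probe sets at an unadjusted p under 0.05 in the real split, and 630, 820 and 1460 in the others that part the pairs. Splits that put both arrays of an assay together gave 994 to 3796 such probe sets without a block by limma against 198 in the real one, which points to the assays as a structure of the samples.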
